A study of Drosophila melanogaster with 12 samples.

How the data were processed

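RNA from testes of 3-day-old Drosophila melanogaster males was measured on 12 Affymetrix Drosophila Genome 2.0 arrays, 3 for each of 4 genotypes. Canton S and BL15598 carry wild-type su(Hw), and A2663/2 and 2/v are heteroallelic su(Hw) nulls. Per the labels' protocols, flies grew at 25°C and 70% humidity, RNA came from about 100 pairs of testes, and 50 ng of it was amplified to cDNA, of which 5 µg was fragmented to about 85 bases and biotin-labelled. The labels call the 3 replicates of a genotype biological, and no 2 arrays held the same values.

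The deposited value of each probe set is an intensity on a linear scale. Partek 6.5 and RMA are named in the submitters' processing notes, whereas the deposited values are linear and each array has the same mean of 1500.03 after trimming 2% of the probe sets from each end, which RMA does not produce. How the deposited intensity values were scaled is therefore open, and the effect of scaling is given beside the counts of higher and lower probe sets. The log2 of the deposited intensity was taken with no offset, and no further normalization was applied. No detection call was used here. Folds are ratios of geometric means, while the signals printed with an SD are arithmetic means. The 183 control probe sets had a median signal of 20.4, and where the dimmer side of a named gene lay below that level its fold is given as a lower bound, from the brighter geometric mean over 20.4. No fold is given where both sides lay below it, or within a pair of genotypes where single arrays of the dimmer side did but their arithmetic mean lay above it. For arrays, the number of arrays limits the precision. The median SD between replicates fell from 1.22 log2 in the dimmest 10% of probe sets to 0.118 in the brightest 10%.

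Genes were named from the platform's annotation, with symbols brought up to date through RefSeq genes of the Release 6 plus ISO1 MT assembly, which was also used for the order of genes along chromosomes. Of 18769 probe sets tested, 13647 had 1 symbol, 402 had several and 4720 had none, which left 11982 named genes. A gene is represented by its probe set with the highest mean over the 12 arrays among those with 1 symbol.

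The log2 values of all 12 arrays were fitted with limma 3.58.1 in R 4.3.3 as 4 genotype means, with empirical Bayes moderation, which leaves 8 residual degrees of freedom before moderation. P-values were two-sided and adjusted by Benjamini-Hochberg over the 18769 probe sets, and a probe set was called at an adjusted p under 0.05. The contrasts were the mean of both nulls against the mean of both wild types, each null against a wild type, wild type against wild type, null against null, and the difference of the effects of the 2 null genotypes. Every adjusted p is from these limma fits unless another test is named. Each gene list was tested with limma's camera at its preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, with adjustment over the 30 lists. The lists were fixed from textbook knowledge of the testis, of neurons and of tissues dissected with the testis, and 448 of their 561 entries were measured.

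The groups, contrasts, tests, gene lists, rule for named genes and alternatives were set before the data were examined, except for the tests and the alternative that are said to have been chosen later. The rule names su(Hw), RpII15, Amt, y, w, ct, f, osk and Rbp9, of which RpII15 and w have no probe set with that symbol alone. It names, among genes called one way in all 4 pairs of a null and a wild type, the 12 per direction with the greatest smallest change over the pairs. It further names up to 4 members per list with the smallest adjusted p, the 6 per direction with the greatest change in each other comparison among called genes whose 3 and 3 values do not overlap, and the 6 per direction with the greatest difference of the 2 null effects. Genes named outside the rule are said to be chosen after their values were seen.

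The fit was tested on simulated values in which 200 probe sets were shifted and the other 18569 were not. Null against wild type, 92% of probe sets shifted by 1 log2 unit were recovered above the median signal and 12% below it, and 6 unshifted ones were called. For a call in all 4 pairs the shares at 1 log2 unit were 64% and 4%, and 0 unshifted ones were called. Each of these shares rests on only 25 shifted probe sets of a single simulated draw. A further simulation drew nulls with no effect of their own. With both nulls at the BL15598 mean, limma called 1442 probe sets null against wild type, and with both at the Canton S mean it called 1474. This simulation took the measured genotype means, with their sampling error, as true. Between the wild types it called 3328 and 3193 probe sets, against 1799 in the data, so it can overstate the part of the stocks.

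Alternatives were median centring of each array, quantile normalization, filters on dim probe sets, a trended and robust prior, array weights, fits on each pair's arrays alone or, null against wild type, on 2 groups of 6 with the genotype ignored, the replicate number as a block, 1 probe set or the mean of all probe sets per gene, stricter thresholds, and leaving out each array in turn. Leaving out the pair of wild-type arrays least like the rest, Canton S replicate 1 and BL15598 replicate 3, was added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.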

Results

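Transcript levels in testes of 3-day-old males were compared between 2 wild-type stocks and 2 su(Hw) null genotypes of Drosophila melanogaster, with 3 arrays each. Canton S is a common laboratory wild type, and BL15598 is a y w stock with a P element at Amt. A2663/2 combines the A2663 and 2 alleles in the y w, Amt-insertion background of BL15598. The other null, 2/v, combines the 2 and v alleles with y, w, ct and f mutations, so both nulls carry allele 2. The comparison asks which testis transcripts depend on Su(Hw), a zinc-finger DNA-binding protein known from the gypsy insulator. Array medians ran from 190 to 242 signal units. Across probe sets, the mean correlation of an array's log2 signals with its own genotype was 0.952 to 0.964, and with other genotypes 0.935 to 0.95.

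**Figure D1:**
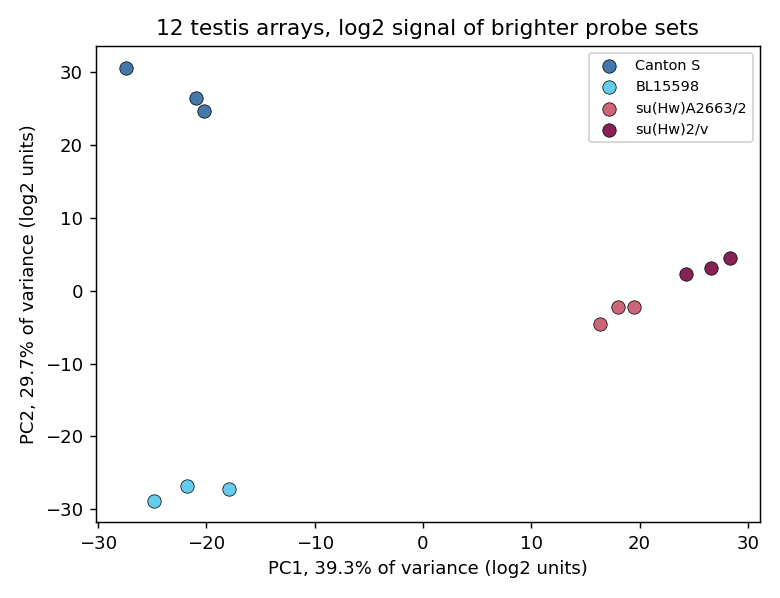
The 12 arrays on the first and second principal components of log2 signal over the brighter probe sets, coloured by genotype, with 39.3% and 29.7% of the variance on the axes. The 6 null arrays lie on 1 side of the first component, and the second separates Canton S from BL15598.

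The signal of su(Hw) itself was 985 ± 191 (SD, n = 3) in Canton S and 1392 ± 161 in BL15598, against 70.1 ± 17.3 in A2663/2 and 42.6 ± 25.6 in 2/v. It fell 22.9-fold in the nulls (log2 change -4.52, SE 0.283, adjusted p = 1.04e-05, lower in 6 of 6 null arrays), with a single 2/v array below the level of the control probe sets. Where its probes lie relative to the lesions of the alleles is not given in the sources used here. Of the other genes fixed for every comparison, osk (log2 0.64, adjusted p = 0.448), Rbp9 (0.17, adjusted p = 0.364), Amt (0.02, adjusted p = 0.977), y (0.16, adjusted p = 0.728), ct (-0.36, adjusted p = 0.37) and f (1.75, adjusted p = 0.0599) did not pass the test null against wild type. The Amt insertion is in BL15598 and A2663/2, and y mutations are in these and 2/v, so this contrast does not test the effect of either. Between the wild types, limma called 0 of 5 stock marker genes.

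Genes with weak signal in both wild types and strong signal in both nulls led the rise. CG6870 went from 208 ± 114 (SD, n = 3) in Canton S and 113 ± 29.3 in BL15598 to 2750 ± 124 in A2663/2 and 3631 ± 46.2 in 2/v, a 22.3-fold rise (log2 4.48, SE 0.279, adjusted p = 1.03e-05). CG11619 rose 21.7-fold (log2 4.44, SE 0.297, adjusted p = 1.55e-05), CG6282 46.1-fold (log2 5.53, SE 0.419, adjusted p = 3.22e-05) and ND-51L2, a paralog of a mitochondrial complex I subunit, 42.5-fold (log2 5.41, SE 0.491, adjusted p = 9.38e-05). The olfactory receptor gene Or22b rose at least 38.5-fold, CG13038 at least 20.9-fold, CG14075 at least 9.98-fold, CG3104 at least 6.12-fold, CG8661 at least 5.38-fold and stol, which encodes a calcium channel subunit, at least 2.43-fold. The cytochrome P450 gene Cyp6a17 rose from 26.8 ± 9.23 in Canton S and 17.2 ± 14.5 in BL15598 to 382 ± 4.72 in A2663/2 and 342 ± 16.4 in 2/v (adjusted p = 0.00189). In CG6282 and ND-51L2 single wild-type arrays lay below the level of the control probe sets, so the sizes are uncertain. The neuropeptide gene sNPF also rose (adjusted p = 0.000604). Its geometric means were 19.5 over the null and 1.05 over the wild-type arrays, both below the 20.4 of the control probe sets, so no size is given. Its A2663/2 arrays, at 45.08, 20.98 and 37.76, lay above that level. Or22b, Cyp6a17 and ND-51L2 have close paralogs, and whether their probes separate these was not tested, so their values are uncertain. CG31321, the next measured gene to su(Hw) and chosen after its values were seen, rose by 1.54 log2 (SE 0.141, adjusted p = 0.000102), while IFT54, the next measured gene on the other side, had a log2 change of -0.24 (adjusted p = 0.522).

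Among genes that fell in both nulls, CG4712 dropped from 17240 ± 1110 (SD, n = 3) in Canton S and 19510 ± 2030 in BL15598 to 3293 ± 701 in A2663/2 and 693 ± 122 in 2/v, a 12.3-fold fall (log2 -3.62, SE 0.127, adjusted p = 6.73e-07). The noncoding RNA lncRNA:CR40465 fell 37.1-fold (log2 -5.21, SE 0.218, adjusted p = 1.02e-06), OS9 17-fold with single null arrays below the level of the control probe sets (log2 -4.09, SE 0.388, adjusted p = 0.000127) and Cyp6a23, the close paralog of Cyp6a17, 8.72-fold (log2 -3.12, SE 0.172, adjusted p = 5.32e-06). Zip102B, of a zinc transporter family, fell 7.42-fold, CG9917 7.63-fold, the serpin gene Spn43Aa 5.89-fold and CG9150 4.73-fold, while CG10257 fell at least 10.1-fold and rumpel at least 3.34-fold. A single 2/v array of CG9150 lay below the level of the control probe sets. The probe set of hbt fell 6.04-fold, but its other probe set rose (log2 0.68, adjusted p = 0.00862). For each of the 24 genes that the rule for all 4 pairs names, su(Hw) among them, the 6 null values lay outside the 6 wild-type values, which chance gives for 0.216% of genes, though the choice favours such genes.

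**Figure D2:**
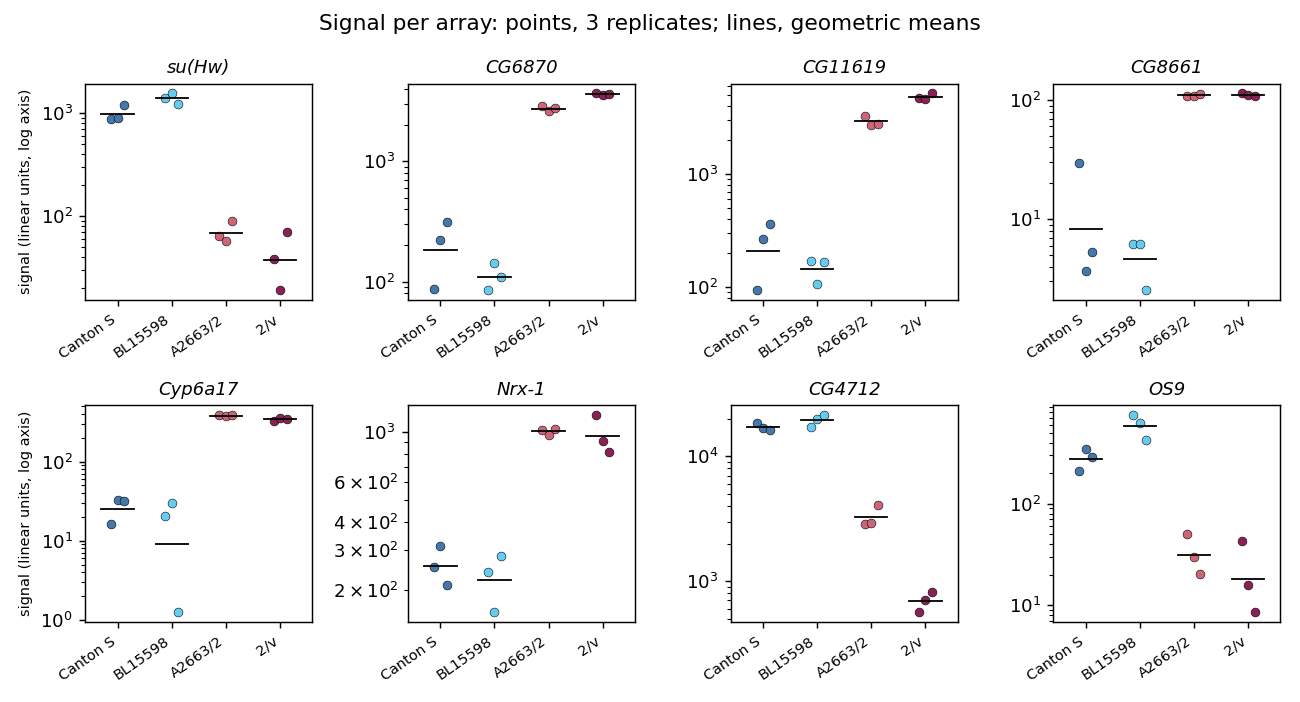
Signal of 8 named genes on a log axis, with 1 point per array and a bar at the genotype mean, for the 3 arrays of each genotype. In each panel the null arrays lie wholly above or wholly below the wild-type arrays.

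Over all probe sets, 384 were called in the same direction in all 4 pairs of a null and a wild type, 285 higher and 99 lower. Counted by the probe set that represents each gene, 292 genes were called so, 209 higher and 83 lower. The mean of both nulls against the mean of both wild types gave 2528 calls, 1664 higher and 864 lower (1173 and 714 genes), of which 930 changed at least 2-fold. The direction of these counts depends on how the arrays are scaled. The share of calls that were higher was 65.8% as deposited, 37.1% with each array centred on its median and 52.1% after quantile normalization, and in all 4 pairs it was 74.2%, 48.6% and 61.2%. Centring shifted the median log2 change of all probe sets from 0.05 to -0.12, and no called value of a gene named by the rule changed sign with scaling, although values without a call did, such as those of Amt and y. A fit of 2 groups of 6 arrays with the genotype ignored gave 1401 calls null against wild type, and fits of each pair's arrays alone gave 195 in all 4 pairs. The 2528 calls rest on the spread between arrays within a genotype, so their number does not show an effect of losing su(Hw). On simulated values with both nulls at the BL15598 or the Canton S mean, limma gave 1442 or 1474 such calls. These simulations called 3328 or 3193 probe sets between the wild types, against 1799 in the data, so they can overstate the part of the stocks. In all 4 pairs they called 0 probe sets. By construction the nulls equalled a wild type in each simulation, so that 0 was fixed in advance. It does not speak to alleles that both nulls share. Counts of list members that rose or fell null against wild type carry the same limit as the 2528 calls.

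Of 19 neuronal ion channel genes measured, 7 rose null against wild type, 0 fell and 12 did not pass, and 1 was called in all 4 pairs, with 9 higher adjusted over the list alone, and limma gave 12 higher and 1 lower at an unadjusted p under 0.05. The calcium channel gene cac rose 2.15-fold (log2 1.11, SE 0.127, adjusted p = 0.000392), the potassium channel genes sei 2.06-fold (log2 1.04, SE 0.144) and Shaw 1.57-fold (log2 0.65, SE 0.0823), and the calcium channel gene Ca-alpha1D 2.65-fold (log2 1.41, SE 0.194). Part of the rise lies in Canton S being low, since the median log2 change of the list was 0.85 in 2/v against Canton S, 0.49 in BL15598 against Canton S and 0.18 in A2663/2 against BL15598. In Ca-alpha1D only Canton S stood apart, at 192 ± 68 against 984 to 1195 in the other genotypes. The list passed fry (fry adjusted p = 4.2e-05), which passed more lists than camera did. It passed camera (adjusted p = 0.0088), but not with an estimated correlation (adjusted p = 0.175 with an estimated correlation), after quantile normalization (adjusted p = 0.0627) or with the mean of all probe sets per gene (adjusted p = 0.112). With that mean cac and Shaw also lost their calls.

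The synaptic adhesion partners Nrx-1, a neurexin, and Nlg2, a neuroligin, rose in all 4 pairs. Nrx-1 went from 260 ± 52.5 (SD, n = 3) in Canton S and 228 ± 61.6 in BL15598 to 1009 ± 35 in A2663/2 and 972 ± 194 in 2/v (4.13-fold, log2 2.05, SE 0.165, adjusted p = 4.49e-05), and Nlg2 rose 2.96-fold (log2 1.56, SE 0.193, adjusted p = 0.000624). The other probe sets of Nlg2 did not pass null against wild type, at log2 0.989 (adjusted p = 0.0863) and 0.0835 (adjusted p = 0.922). Of 19 axon guidance and synaptic adhesion genes 6 rose, 0 fell and 13 did not pass, with 7 higher adjusted over the list alone and 9 higher by limma at an unadjusted p under 0.05 (camera adjusted p = 0.0827). Of 20 synaptic vesicle genes 4 rose, 1 fell and 15 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.129). Rph, the rabphilin gene, rose 5.91-fold (log2 2.56, SE 0.14, adjusted p = 5.32e-06), the v-SNARE gene nSyb 1.81-fold and the synaptotagmin gene Sytalpha 1.81-fold, and the proton pump subunit gene Vha100-1 fell 1.43-fold. Among 35 neurotransmitter genes 3 rose, 2 fell and 30 did not pass, with 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.879). GABA-B-R1 rose 2.04-fold and the dopamine transporter gene DAT fell 2.98-fold, with Canton S at 207 ± 8.31 and the other genotypes at 32 to 41.6. A single 2/v array of DAT lay below the level of the control probe sets. Of 12 neuronal RNA-binding and transcription genes 2 rose, 1 fell and 9 did not pass, with 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.919), and the homeobox gene pros rose 2.6-fold (log2 1.38, SE 0.317, adjusted p = 0.0183).

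Among spermatocyte transcription regulators, the near-identical homeobox genes achi and vis went opposite ways. The probe set of achi rose 4.95-fold (log2 2.31, SE 0.237, adjusted p = 0.000212) and that of vis fell 1.9-fold (log2 -0.93, SE 0.0879, adjusted p = 0.000128), and as whether their probes separate the paralogs was not tested both values are uncertain. The testis TAF gene Taf12L fell 1.54-fold, a call lost with the mean of its probe sets, and mia, another testis TAF gene, rose 1.41-fold. Of the 17 regulators 3 rose, 5 fell and 9 did not pass, the same adjusted over the list alone (camera adjusted p = 0.572). Of 27 spermatid differentiation genes 1 rose, 1 fell and 25 did not pass, the same adjusted over the list alone (camera adjusted p = 0.577), dj rising 1.42-fold and nsr falling 1.32-fold, though centring ended the call of dj, in which only Canton S stood apart, at 8371 against 12650 to 15390. Of 17 cup and comet genes, transcribed after meiosis, limma called 0 over all probe sets or adjusted over the list alone and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.991). Of 16 individualization genes 2 fell and 14 did not pass, the same adjusted over the list alone, with 1 higher and 4 lower at an unadjusted p under 0.05 (camera adjusted p = 0.572). Of 7 Y-linked fertility genes 2 rose, 1 fell and 4 did not pass, the same adjusted over the list alone (camera adjusted p = 0.572). Ppr-Y rose 1.5-fold (log2 0.59, SE 0.0862, adjusted p = 0.00174), and the dynein gene kl-2 fell 1.26-fold, a direction that the mean of its probe sets does not share.

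In the early germline, the gap junction gene zpg rose 1.6-fold (log2 0.68, SE 0.0904, adjusted p = 0.000964), with BL15598 at 133 ± 11.1 (SD, n = 3) and the other genotypes at 247 to 295. Of 18 germline stem cell and spermatogonium genes 2 rose, 0 fell and 16 did not pass, with 1 higher adjusted over the list alone, and limma gave 2 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.753). Of 22 piRNA pathway genes 1 rose, 4 fell and 17 did not pass, the same adjusted over the list alone (camera adjusted p = 0.403). In that list cuff rose 1.56-fold, and spn-E (1.31-fold), tej (1.33-fold) and krimp (1.32-fold) fell. The E-cadherin gene shg fell 1.59-fold (log2 -0.67, SE 0.148, adjusted p = 0.0149). It was the only call among 7 hub cell genes, of which 2 were lower adjusted over the list alone (camera adjusted p = 0.277). Of 11 cyst cell genes limma called 0, also adjusted over the list alone, and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.964). Of 9 JAK-STAT genes 1 rose, 2 fell and 6 did not pass, the same adjusted over the list alone (camera adjusted p = 0.919). In it the repressor gene ken rose 2.12-fold (log2 1.09, SE 0.117, adjusted p = 0.000278), the receptor gene et fell 3.37-fold and Ptp61F fell 1.25-fold, a direction that the mean of its probe sets does not share. A single A2663/2 array of et lay below the level of the control probe sets, so the size of its fall is uncertain. Of 9 EGFR genes 1 rose, 0 fell and 8 did not pass, the same adjusted over the list alone and at an unadjusted p under 0.05 in limma (camera adjusted p = 0.964), and that gene, aos, rose 1.79-fold. Of 15 BMP and Hedgehog genes limma called 0, also adjusted over the list alone, and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.885).

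Among 14 insulator and architectural proteins su(Hw) fell, 3 rose and 10 did not pass, with 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.747). Ibf1 rose 1.54-fold (log2 0.62, SE 0.138, adjusted p = 0.0155), Elba2 1.53-fold and Ibf2 1.33-fold, but quantile normalization ended the call of Elba2 and centring that of Ibf2, in which only Canton S stood apart, at 3903 against 6056 to 6962 in the other genotypes. Of 5 stock marker genes su(Hw) fell and 4 did not pass, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.643).

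Markers of tissues next to the testis were mixed. Of 21 accessory gland proteins limma called 0, also adjusted over the list alone, and 1 at an unadjusted p under 0.05, with a median log2 change of 0.68 (camera adjusted p = 0.129, and 0.0107 after centring, but adjusted p = 0.893 with an estimated correlation). Their mean log2 signal ranged from 9.35 to 11.5 over the 12 arrays, with Canton S replicate 1 lowest and 2/v replicate 1 highest. Of 18 muscle sheath genes 0 rose, 3 fell and 15 did not pass, with 1 higher and 6 lower adjusted over the list alone, and limma gave 1 higher and 7 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0895). The tropomyosin gene Tm2 fell 1.42-fold (log2 -0.51, SE 0.104, adjusted p = 0.0102), and the probe set of Mf, which encodes myofilin, fell 1.38-fold with BL15598 apart, but its other probe set rose (log2 0.60, adjusted p = 0.00215), with BL15598 lowest. Of 14 fat body genes 4 rose, 1 fell and 9 did not pass, with 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.885). The odorant-binding protein gene Obp99b rose 6.26-fold (log2 2.65, SE 0.203, adjusted p = 3.42e-05), Lsp2 rose 1.66-fold, Fbp2 rose 1.77-fold and Obp99a fell 1.33-fold. Of 11 hemocyte genes 1 rose, 0 fell and 10 did not pass, the same adjusted over the list alone and at an unadjusted p under 0.05 in limma (camera adjusted p = 0.513), and that gene, the GATA factor gene srp, rose 1.49-fold. Of 5 ejaculatory duct and bulb genes limma called 0, also adjusted over the list alone, and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.847). Of 15 gut and Malpighian tubule genes 1 rose, 2 fell and 12 did not pass, the same adjusted over the list alone (camera adjusted p = 0.847). Of 18 ovary and egg genes only the eggshell gene dec fell (1.46-fold), also adjusted over the list alone, and limma gave 1 at an unadjusted p under 0.05 (camera adjusted p = 0.847).

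Of 15 detoxification genes 4 rose, 2 fell and 9 did not pass, the same adjusted over the list alone (camera adjusted p = 0.847). GstD5 rose 1.75-fold, with BL15598 lowest at 1442 ± 94.8 (SD, n = 3), and Cyp6a8 fell 3.74-fold, with Canton S highest at 218 ± 90.2. Single null arrays of Cyp6a8 lay below the level of the control probe sets, so the size of its fall is uncertain. Of 13 immune genes 1 rose, 0 fell and 12 did not pass, with 0 adjusted over the list alone, and limma gave 4 higher at an unadjusted p under 0.05 (camera adjusted p = 0.747). Of 5 heat shock genes limma called 0, with 3 lower adjusted over the list alone and at an unadjusted p under 0.05 (camera adjusted p = 0.208). Of 10 cell death and DNA damage genes limma called 0, also adjusted over the list alone, and 5 at an unadjusted p under 0.05, 2 higher and 3 lower (camera adjusted p = 0.885). Median, mean and camera test differed in sign for the stock marker, neuronal RNA-binding, cyst cell, spermatocyte regulator, cup and comet, JAK-STAT, EGFR, ejaculatory duct, ovary and cell death lists. The mean log2 change of a list turned sign with centring or quantile normalization for the neurotransmitter, cyst cell, germline, spermatocyte regulator, spermatid differentiation, cup and comet, Y-linked, JAK-STAT, EGFR, BMP and Hedgehog, ovary and cell death lists, while that of the ion channels was 0.66 as deposited, 0.49 centred and 0.50 after quantile normalization. As signs of RNA quality, the log2 ratio of 3' to 5' signal was 2.51 ± 0.207 (SD, n = 6) in null and 2.90 ± 0.625 in wild-type arrays for Act5C (two-sided exact permutation p = 0.136), 2.82 against 3.11 for Gapdh (exact permutation p = 0.169) and 3.94 against 4.35 for eIF4A (exact permutation p = 0.32). These permutations ignored the genotype. Act5C means were 2.55 in Canton S, 3.24 in BL15598, 2.41 in A2663/2 and 2.62 in 2/v, so only BL15598 stood apart. In the same order they were 2.96, 3.26, 2.78 and 2.86 for Gapdh and 4.35, 4.35, 3.84 and 4.05 for eIF4A. BL15598 replicate 3 had the highest of the 12 ratios, at 4.12 for Act5C and 5.82 for eIF4A.

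**Figure D3:**
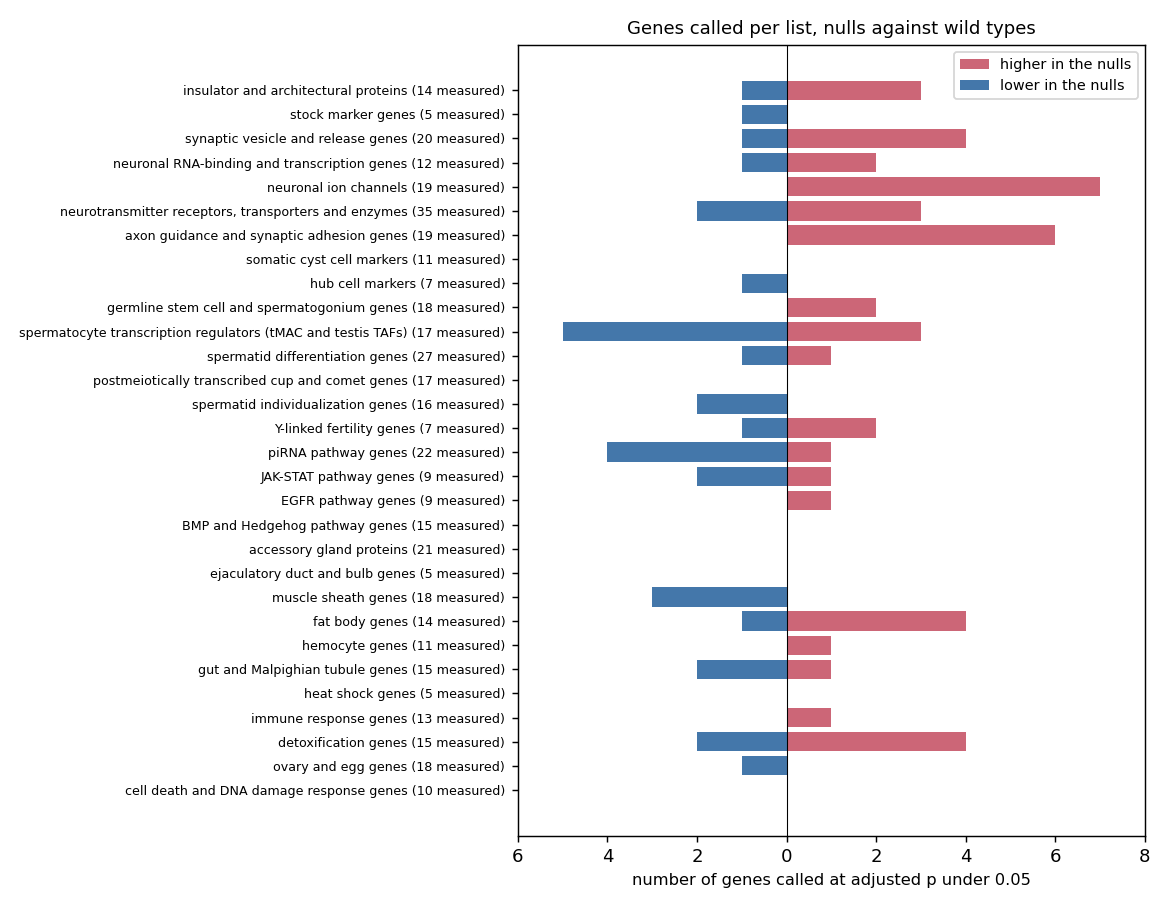
For each of the 30 gene lists, the number of members called higher (right) and lower (left) in the nulls on the x axis, with the number measured beside its name. The neuronal ion channel list has 7 members higher and 0 lower of 19.

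In the pair with matched labels, A2663/2 against BL15598, CG42792 and CG3397 rose to levels near those of Canton S. CG42792 was at 4.98 ± 1.11 (SD, n = 3) in BL15598 and 389 ± 18 in A2663/2 (at least 19-fold, adjusted p = 1.7e-07), but 326 ± 31.5 in Canton S. CG3397 was at 7.78 ± 4.19 in BL15598, 534 ± 44.6 in A2663/2 and 747 ± 8.92 in Canton S, and the acylphosphatase gene Acyp at 392 ± 423, 12630 ± 513 and 12740 ± 645. Or22b (at least 31.7-fold), ND-51L2 (adjusted p = 0.000513) and CG6282 (adjusted p = 0.000403) also rose, and CG33476 (at least 3.96-fold), su(Hw) (20.2-fold), OS9 (18.7-fold) and lncRNA:CR40465 (14-fold) fell. CG13946 and CG8837 fell from high levels seen only in BL15598, 17580 ± 5700 against 991 ± 310 in A2663/2 (log2 -4.15) and 812 ± 165 against 38 ± 21.9 (log2 -4.55). There were 1281 calls, 819 higher and 462 lower, and BL15598 differed from all 3 other genotypes in 468 of them (36.5%). The ion channel list had 1 gene higher and 18 not passed (camera adjusted p = 0.298), and the axon guidance list 2 and 17 (camera adjusted p = 0.505). The share of higher calls was 63.9% as deposited, 47% centred and 55.4% after quantile normalization. The count was 808, 848 and 798 without A2663/2 replicate 1, 2 or 3, and 655 with these arrays fitted alone.

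In 2/v against Canton S, CG10700 and CG13038 rose from signals below the level of the control probe sets. CG10700 was at 7.17 ± 6.41 (SD, n = 3) in Canton S and 842 ± 78.3 in 2/v (at least 41.1-fold, adjusted p = 0.000129), but 841 ± 197 in BL15598. CG13038 (at least 34-fold), Or22b (adjusted p = 0.00217), CG6282 (40.4-fold), CR11023 (33.7-fold) and the serine protease gene Jon99Fi (at least 3.23-fold) rose as well. CG12498 fell from 3634 ± 329 to 22.3 ± 15.6 (adjusted p = 0.000286), with BL15598 at 30.4 ± 20, and CG3526 (adjusted p = 0.00995) and CG14369 (43.7-fold lower in 2/v) likewise were high in Canton S alone. CG9825 fell in 2/v to 12.4 ± 12.2 from 793 ± 11.6 (at least 38.8-fold), and lncRNA:CR40465 (98.3-fold) and CG18682 (43.2-fold) fell too. There were 1957 calls, 1284 higher and 673 lower, and Canton S differed from all 3 other genotypes in 621 of them (31.7%). In this pair 8 ion channel genes rose and 11 did not pass (12 adjusted over the list alone, camera adjusted p = 0.00185, adjusted p = 0.0999 with an estimated correlation and 0.0892 with the mean of all probe sets per gene). Of the axon guidance genes 7 rose and 12 did not pass (8 adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.346 with an estimated correlation), and that list also lost its call after quantile normalization (adjusted p = 0.056), with the mean of all probe sets per gene (adjusted p = 0.0892) and without 2/v replicate 3 (adjusted p = 0.0865). The share of higher calls was 65.6% as deposited, 40% centred and 51.9% after quantile normalization.

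These pairs share no array, and su(Hw), Nrx-1, Rph, Obp99b and CG11619 are among the genes called the same way in both. Together 502 probe sets were called in the same direction, 361 higher and 141 lower, where independent lists of those lengths would share 56 and 16.6. Opposite calls numbered 39 higher in A2663/2 and lower in 2/v and 34 the other way, against 29.4 and 31.6 for independent lists. Across probe sets, which are not independent replicates, the log2 changes of the pairs correlated with r = 0.265, and with r = 0.417 among probe sets brighter than the median. The share of shared calls that were higher was 71.9% as deposited, 46.7% centred and 58.5% after quantile normalization. With each pair fitted alone the shared calls numbered 239.

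**Figure D4:**
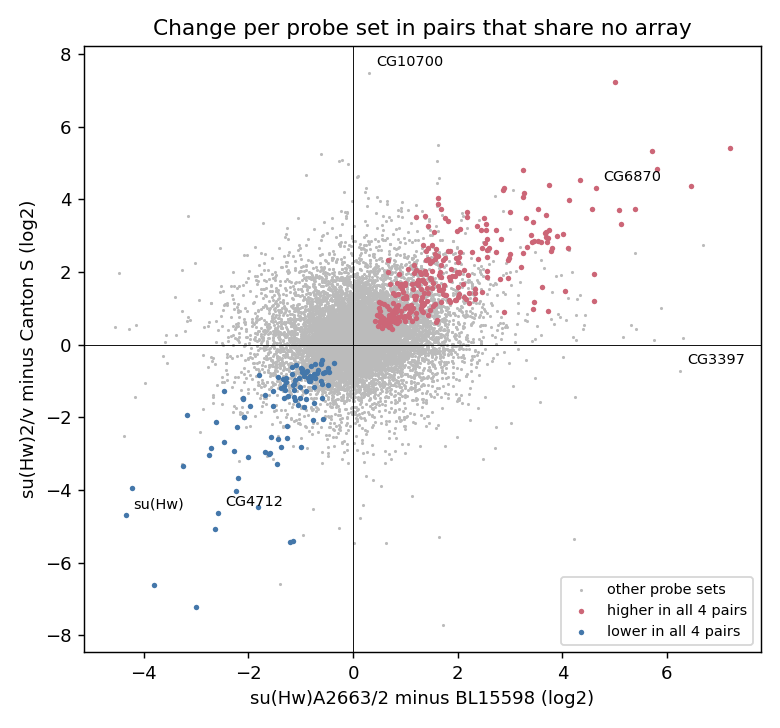
Log2 change of each probe set in A2663/2 against BL15598 on the x axis and in 2/v against Canton S on the y axis, with the 384 probe sets called one way in all 4 pairs marked. These lie in the upper right (285) and lower left (99) of the plot.

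The wild-type stocks differed widely. CG10700 (at least 40.4-fold), CG14147 (at least 14.8-fold), CR11023 (35.5-fold) and Elovl7 (at least 5.6-fold) were higher in BL15598 than in Canton S, CG14147 at 309 ± 66.4 (SD, n = 3) against 8.39 ± 2.92. CG13946 (29.1-fold) was higher as well, as was the peroxidase gene Pxd (at least 1.47-fold), a call lost without Canton S replicate 2 (adjusted p = 0.0584) or BL15598 replicate 2 (adjusted p = 0.051). Lower in BL15598 were CG12498 (adjusted p = 0.000462), CG14369 (63.4-fold), Acyp (54.8-fold), CG31269 (at least 54.5-fold), CG3397 (at least 36.6-fold) and CG42792 (at least 15.9-fold). There were 1799 calls, 1019 higher and 780 lower, and 715 with these arrays fitted alone. The share of higher calls was 56.6% as deposited, 48.3% centred and 50.5% after quantile normalization. No gene list passed camera between the stocks, the lowest being the ion channels with 4 genes higher and 15 not passed (adjusted p = 0.202).

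The null genotypes differed least. DIP-delta, an immunoglobulin-domain gene, was at 229 ± 22.2 (SD, n = 3) in 2/v and 7001 ± 426 in A2663/2, with the wild types at 7489 ± 223 and 8453 ± 694 (log2 -4.94, SE 0.11, adjusted p = 4.94e-08), although with the mean of its probe sets a call of it was lost. CG9825 (at least 37.4-fold), CG9801 (17.7-fold, log2 -4.14, SE 0.173), CG33272 (15.2-fold, log2 -3.92, SE 0.234), Eig71Ef (at least 8.83-fold) and the ionotropic receptor gene Ir94a (at least 4.18-fold) were lower in 2/v too. The cuticle protein gene Cpr67Fa2 was higher in 2/v, at 648 ± 111 against 110 ± 11.2 (log2 2.55, SE 0.153, adjusted p = 8.32e-05), as were CG33099 (log2 2.77, SE 0.184) and CG5715 (at least 4.14-fold). The higher calls of mas, Sox21a and CG13084 were each lost when single arrays were left out. There were 174 calls, 66 higher and 108 lower (60 and 112 centred, 74 and 130 after quantile normalization). Leaving out a null array gave 107, 97 and 92 without A2663/2 replicate 1, 2 or 3 and 104, 94 and 101 without 2/v replicate 1, 2 or 3, and these arrays fitted alone gave 85.

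The change against the pair's own wild type differed between the null genotypes for 5 of the 12 genes that the rule for all 4 pairs names as lower. CG4712 fell by 2.58 log2 in A2663/2 against BL15598 and by 4.65 in 2/v against Canton S (difference 2.07, SE 0.254, adjusted p = 0.0019). For lncRNA:CR40465 the log2 changes were -3.81 and -6.62, and for Cyp6a23 -2.23 and -4.02, where the nulls did not pass (adjusted p = 0.511) and Canton S was the higher wild type. The difference of the effects was called for 763 probe sets, 357 positive and 406 negative (406 and 335 centred, 468 and 409 after quantile normalization), and for 500 without A2663/2 replicate 3.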

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

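The tests on the ion channel list were chosen only after the result was seen, and they are given under the other observations, while the tests in this part were planned.

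The change in A2663/2 against BL15598 differed from that in 2/v against Canton S for 763 probe sets in limma's test of the difference itself, and positive differences mean a more positive change in A2663/2. Of the 12 genes that the rule for all 4 pairs names as lower, 5 fell further in 2/v: lncRNA:CR40465 by 2.81 log2 (SE 0.436, adjusted p = 0.00624), CG10257 by 2.45 (SE 0.575, adjusted p = 0.0484), CG4712 by 2.07 (SE 0.254, adjusted p = 0.0019), Cyp6a23 by 1.79 (SE 0.344, adjusted p = 0.0195) and CG9917 by 1.45 (SE 0.281, adjusted p = 0.0201). The signal of CG10257 in 2/v lay below the level of the control probe sets, so the size of its difference is uncertain. Between the nulls themselves CG10257 (adjusted p = 0.0581) and Cyp6a23 (adjusted p = 0.511) did not pass, while for Cyp6a23 the wild types differed (log2 -1.20, adjusted p = 0.0134). The positive differences that the rule names were CG31269 at 9.56 (SE 0.795), CG12498 at 9.42 (SE 1.15), CG3397 at 6.98 (SE 0.473), CG17477 at 6.94 (SE 1.25), CG42792 at 6.15 (SE 0.244) and CG14369 at 6.08 (SE 0.567). The negative ones were CG10700 at -7.15 (SE 0.98), CG14147 at -5.33 (SE 0.366), CR11023 at -5.29 (SE 1.09), Elovl7 at -5.07 (SE 0.534), the glutamate decarboxylase gene Gad1 at -5.07 (SE 0.983) and CG8837 at -5.02 (SE 0.775). In 9 of these 12 genes at least 1 genotype lay below the level of the control probe sets, so the sizes and their order are uncertain, and the exceptions are CG14369, CR11023 and CG8837. Only CG31269 among these 12 was called in both pairs, rising by 4.22 log2 in A2663/2 against BL15598 and falling by 5.34 in 2/v against Canton S. Each pair has its own wild type, so this difference mixes the null alleles with the stocks. As the stocks are mixed in, the count does not show that the effect of losing su(Hw) differed. On simulated values with both nulls equal, at the BL15598 or the Canton S mean, the same test called 1503 or 1325 probe sets. Those simulations called 3328 or 3193 probe sets between the wild types, against 1799 in the data. They can overstate the part of the stocks and do not size it among the 763.

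Random assignment of arrays does not account for the counts that use all 12 arrays. Of 100 drawn assignments of the arrays to 4 groups of 3, only the real one, 1 of 100, gave as many calls null against wild type (2528, highest other 113), in all 4 pairs (384, highest other 0), in both pairs that share no array (502, highest other 0) and for the difference of the null effects (763, highest other 161). The draws mix genotypes within a group, which raises the spread. They therefore show that genotypes differ, but not that the differences follow su(Hw) status. On simulated values with both nulls at 1 wild-type mean, limma gave 1442 or 1474 calls null against wild type and 1503 or 1325 for the difference. These simulated counts can overstate the part of the stocks. For the number of gene lists called chance cannot be excluded, since 70 of 100 assignments gave at least the real 1, and the highest other gave 6. Within a pair the 10 splits of 6 arrays are too few for a share under 0.05. The real values and highest others were 1281 and 0 for A2663/2 against BL15598, 1957 and 2 for 2/v against Canton S, 1799 and 4 for the wild types and 174 and 1 for the nulls.

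More probe sets were called higher than lower in the nulls, 65.8% null against wild type. Array scaling is a candidate cause, since the share that was higher fell to 37.1% after median centring and to 52.1% after quantile normalization. Dim probe sets with unreliable signal cannot be told apart from other causes, as above the median signal the share was 60%, on the bound set for the test, and below it 77.1%. These shares also depend on scaling. Above the median signal the share was 28.2% centred and 51% after quantile normalization, and below it 59.4% and 54.8%. A true excess of activated genes, which the design's null groups would allow, also stays open, as untested.

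In 468 of the 1281 calls of A2663/2 against BL15598, BL15598 stood apart from the other 3 genotypes, and in 621 of the 1957 calls of 2/v against Canton S, Canton S did. A sequence variant under the probes in 1 stock may contribute, but cannot be told apart from a difference in transcript level: where the gene had another bright probe set, it showed the same pattern in 31.5% of cases (23 of 73), between the bounds set for the test. A difference between the stocks' genomes or rearing stays open, as untested.

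For the genes changed one way in all 4 pairs, alleles close to su(Hw) on the chromosome with allele 2 are argued against as the general cause: 5.26% of these genes lie among the 500 measured genes on either side of su(Hw), where 8.4% of all measured genes lie. Both nulls may share alleles further along that chromosome, outside this window, and the test cannot speak to those. Nor does it clear single genes such as CG31321. A sequence variant under the probes shared by both nulls is a candidate explanation for part of them, as another bright probe set of the gene was called the same way in all 4 pairs in 10% of cases (2 of 20). Missed calls would also lower that share, since only 64% (16 of 25) of bright simulated probe sets shifted by 1 log2 unit were recovered in all 4 pairs. For calls null against wild type the share was 29.3% (48 of 164). The test in all 4 pairs covers 20 of the 384 probe sets, and the other probe set changed in the same direction, called or not, in 23 of 38 cases. A response to loss of Su(Hw), which the design's groups allow, stays open for the rest.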

How the results depend on the processing

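Leaving out the 2 least similar wild-type arrays was chosen after seeing the data. The other alternatives were planned. Of 218 counts under an alternative 171 stayed within 1.5 times their main value, and of 3961 values of named genes 3691 kept their direction and side of the threshold, 40 without a call before or after changed sign (5 with centring and 4 with quantile normalization), 184 lost a call, 43 gained one and 3 reversed. The reversals came with the mean of all probe sets per gene, kl-2 at 0.0693 (adjusted p = 0.779), Ptp61F at 0.0386 (adjusted p = 0.796) and Mf at 0.0675 (adjusted p = 0.576), and for these as for other results that changed the cause was not tested, except where fewer arrays or a stricter threshold leave fewer calls by construction.

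With 2 groups of 6 and the genotype ignored limma called 1401 probe sets null against wild type, and with only each pair's arrays 195 in all 4 pairs, 655 for A2663/2 against BL15598, 239 in both array-independent pairs, 715 between the wild types and 85 between the nulls. At an adjusted p under 0.01 the counts were 1340, 199, 609, 242, 929 and 75 in that order, with 1019 for 2/v against Canton S and 339 for the difference of the null effects. With a 2-fold minimum they were 930, 226, 739, 288 and 958, and 1123 for 2/v against Canton S. A filter on the highest group mean gave 263 between the nulls and 1275 for the difference, a trended and robust prior 1152 for the difference, and array weights 1958 for A2663/2 against BL15598, 318 between the nulls and 1197 for the difference. The number of gene lists called was 0 with an estimated correlation, with the mean of probe sets and with quantile normalization (lowest adjusted p 0.175, 0.0796 and 0.0627, with 2, 6 and 5 at an unadjusted p under 0.05), 3 with centring, 8 with fry, and 2 without the 2 arrays. The 8 with fry were the stock marker, synaptic vesicle, ion channel, axon guidance, hub cell, Y-linked, muscle sheath and heat shock lists. Leaving out 1 array at a time gave 798 to 1264 calls for A2663/2 against BL15598, 92 to 187 between the nulls, 500 to 759 for the difference and 1 to 4 gene lists. Without the 2 arrays 2023 of the 2528 probe sets called null against wild type and 280 of the 384 called in all 4 pairs were called again. With the replicate number as a replicate block 2359 probe sets were called null against wild type, and residuals of same-numbered arrays of different genotypes correlated above 0.1 in 6 of 18 pairs, against 10 of 36 for different numbers. What signal limits is precision: on simulated values 12% (3 of 25) of dim and 92% (23 of 25) of bright probe sets shifted by 1 log2 unit were recovered.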

Other observations

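The tests of the ion channel list against lists matched on brightness and against other neuronal genes, and the families of genes with a shared symbol prefix, were chosen only after the result was seen.

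In the order of measured genes, those changed in all 4 pairs lay next to each other more often than shuffled calls did. There were 11 pairs of neighbouring genes called the same way, against a median of 4 and a 95th percentile of 8 in 10000 shuffles (permutation p = 0.002). In that order CG14075 (log2 3.65) lies next to CG11619 (4.44), CG6870 (4.48) next to Sytalpha (0.86), CG14826 (2.75) next to CG14829 (1.21), and Mp20 (-0.85) next to CG4712 (-3.62). A hypothesis is that loss of Su(Hw) may change expression over stretches of more than 1 gene, and the 11 pairs meet its prediction without singling it out. The shuffles treat neighbouring genes as independent, and the same count was not made for calls between the wild types. Overlapping transcripts or probes, or linked alleles that both nulls share, would also give such pairs, which was not tested.

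The ion channel genes' median log2 change, 0.55 null against wild type, lay at the 99.89th percentile of 10000 random lists matched on mean signal, which argues against brightness as the cause of the rise. In A2663/2 against BL15598 the list lay at percentile 84.78 and in 2/v against Canton S at 99.99. The wider hypothesis, that neuronal genes as a whole are higher in both nulls, did not pass its test: without the ion channels, the 86 genes of the other neuronal lists lay at percentile 98.53 null against wild type and 97.51 in 2/v against Canton S, but at 79.69 in A2663/2 against BL15598. In that pair neither the ion channels nor the other neuronal genes passed the 95th percentile.

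Among 53 families of genes that share a symbol prefix, the neprilysin-like Nepl genes passed camera in 2/v against Canton S, where 7 of 19 rose, 0 fell and 12 did not pass (adjusted p = 0.00941, adjusted p = 0.968 with an estimated correlation). Null against wild type 5 rose and 0 fell (adjusted p = 0.411), and in A2663/2 against BL15598 1 rose and 2 fell. Between the wild types 5 were higher and 1 lower in BL15598 (median log2 0.61, adjusted p = 0.138), against a median of 0.84 in 2/v against Canton S. Of 20 Nup nucleoporin genes 3 fell, 0 rose and 17 did not pass null against wild type, and of 12 Prosbeta proteasome genes 2 fell, 0 rose and 10 did not pass (adjusted p = 0.0859 for each).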
